A study of Arabidopsis thaliana with 16 samples.

How the data were processed

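Polyadenylated mRNA was extracted from roots and shoots of 10 day old wild-type Arabidopsis thaliana seedlings, per the labels' protocols. They grew for 4 days at 22 °C and for 6 days after transfer to 22 °C, to 32 °C, or to a regime with the shoot at 32 °C and a root zone whose temperature falls with depth. One table of 32833 loci and 16 columns was deposited. Its values are a score, namely the authors' normalised counts as whole numbers, and how the authors normalised them is not given in the sources used here. The submitters' processing notes name STAR 2.5.3a, HISAT2 and DESeq2 with no role or order. Genome build, annotation and treatment of strand and of reads shared between gene copies are not given in the sources used here. Values of near-identical genes, such as LHCB1.1, PHT1;1 with PHT1;2, RBCS1B, BIP1 and VSP1 with VSP2, are therefore uncertain, and so are those of overlapping and antisense genes. Gene names were taken from a TAIR10.1 table through the locus codes. It matched 32548 loci, and the 285 not matched were all chloroplast or mitochondrial. No coordinates are given because the authors' build is not known.

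Column totals lay between 33075029 and 34769425. Read depth itself is unknown, so no counting intervals were computed. Low values were checked for the gaps and doubled values that scaling by 1 factor and rounding leaves. Their dispersion against neighbouring values was 0.83 to 1.2 as deposited, and 1.35 to 5.56 once the values were scaled by factors from 0.8 to 1.05 and rounded. The values thus show no trace of such scaling, but they do not tell how the authors normalised them. Tests for read counts were not used, because the authors call the values normalised, and whether the whole numbers are reads stays open.

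Columns were compared before any test. Replicates 1 and 2 of the 22 °C roots were equal at all 32833 loci, as were replicates 2 and 3 of the gradient shoots, and each pair was counted as 1 library, so that 14 distinct libraries remained. The design fixed before the data were examined had assumed 8 libraries per organ. The 22 °C root group holds 1 library, which was assumed to vary like the other root groups. Residual degrees of freedom were 4 in each organ and 8 in the fit of both organs.

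Values were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1). Each organ had 1 fit with a mean per regime, an intensity trend in the variance and moderated two-sided tests. Genes with a value of at least 10 in at least 2 columns of the organ were tested, identical columns included. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 were called. The difference between root and shoot in each contrast was tested as an interaction in 1 fit of all libraries. Tables were handled with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

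A set of 27 gene lists with 477 members was fixed before the data were examined. Lists with at least 3 tested members were set against other genes with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. No list call at the preset correlation held with the estimated one. The fry test, which asks whether members move one way without setting them against other genes, was an alternative.

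Genes were named by a rule fixed beforehand. Per comparison it allowed the 8 called genes with the largest rise and the 8 with the largest fall, among genes with a mean of at least 50 in the higher group and no overlap between the groups' libraries. From each list described it allowed up to 5 called and 3 uncalled members by adjusted p, and it added fixed genes that are reported whatever their result. The rule allowed 440 loci, of which 126 were kept for the text after their values had been seen. This choice also set which single genes were compared between organs in the closing section.

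Alternatives fixed beforehand were pseudocounts of 0.5 and 8, no filter on low values, TMM factors within the organ (log-ratio trim 30%, intensity trim 5%), equal totals within the organ, library weights, all libraries in 1 fit, only the 2 groups compared, a minimum fold change of 2, the replicate number as a block, and leaving out each library in turn. Identical columns kept as separate replicates, and voom weights with TMM factors, were chosen after seeing the data. So were the blocks that number the 22 °C root library 1 or 2 and the pair of identical gradient shoot columns 3, and a filter that counts identical columns once. Overlaps between contrasts that share libraries were set beside 100 simulations of unchanged groups and beside independent lists of the same sizes.

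Same-numbered libraries were checked for shared deviations from their group means. Between 32 °C roots and 32 °C shoots the correlations across genes of all 3 pairs lay between 0.20 and 0.33, so these numbers pair the organs by the criterion set beforehand, a correlation over 0.1 in every pair. The pairing comes from the values, since the labels do not state one. Within an organ no set of 3 pairs met it, and the comparisons within organs were not treated as paired.

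The procedure was tested on simulated data of 21877 genes with known changes. For 1.5-fold, 2-fold and 4-fold changes it recovered 28.4%, 67.2% and 92.4% in the comparison of 32 °C with 22 °C roots, 32.8%, 82.1% and 92.4% in gradient against 22 °C roots, and 64.2%, 88.1% and 97% in gradient against 32 °C roots. In shoots it recovered 68.7%, 89.6% and 93.9% at 32 °C against 22 °C, 68.7%, 85.1% and 95.5% in the gradient against 22 °C, and 67.2%, 88.1% and 100% in the gradient against 32 °C. Between 3 and 11 unchanged genes were called. Only 66 or 67 genes changed per fold size, as many up as down overall. Each gene was given the median spread of genes of like abundance. In the data many more genes were called, mostly in 1 direction, and spread differs by gene. The recovered shares are therefore not the shares of real changes that the comparisons could find.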

Results

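Polyadenylated mRNA from roots and shoots of wild-type Arabidopsis thaliana seedlings was measured by RNA-seq. Seedlings spent 4 days at 22 °C and then 6 days under 1 of 3 regimes. These were 22 °C for the whole plant, 32 °C for the whole plant, and a gradient regime in which the shoot was at 32 °C while the root zone grew cooler with depth. The deposited table had 2 columns per organ at 22 °C and 3 per organ for each of the other regimes, 16 in all. Replicates 1 and 2 of the 22 °C roots held the same value at each of 32833 loci, and so did replicates 2 and 3 of the gradient shoots. Separate libraries would differ by sampling noise alone, so each of these pairs was counted as 1 library and 14 remained. Roots were represented by 1 library at 22 °C, 3 at 32 °C and 3 in the gradient, and shoots by 2, 3 and 2. Other pairs of replicates were equal at 6644 to 9019 loci. The column totals of normalised read counts lay between 33075029 and 34769425, and the number of reads behind them was unknown because only normalised values were used.

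Markers of green tissue separated the organs. The light-harvesting gene LHCB1.1 (AT1G29920) reached 200200 ± 8200 (SD, n = 2) normalised counts in 22 °C shoots and 44 in the 22 °C root library. In the gradient roots it stood at 7 and 18 in replicates 1 and 2 and at 290 in replicate 3. Group values below are mean normalised read counts ± SD over libraries, and the single 22 °C root library has no SD and was taken to vary like the other root groups. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

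**Figure D1:**
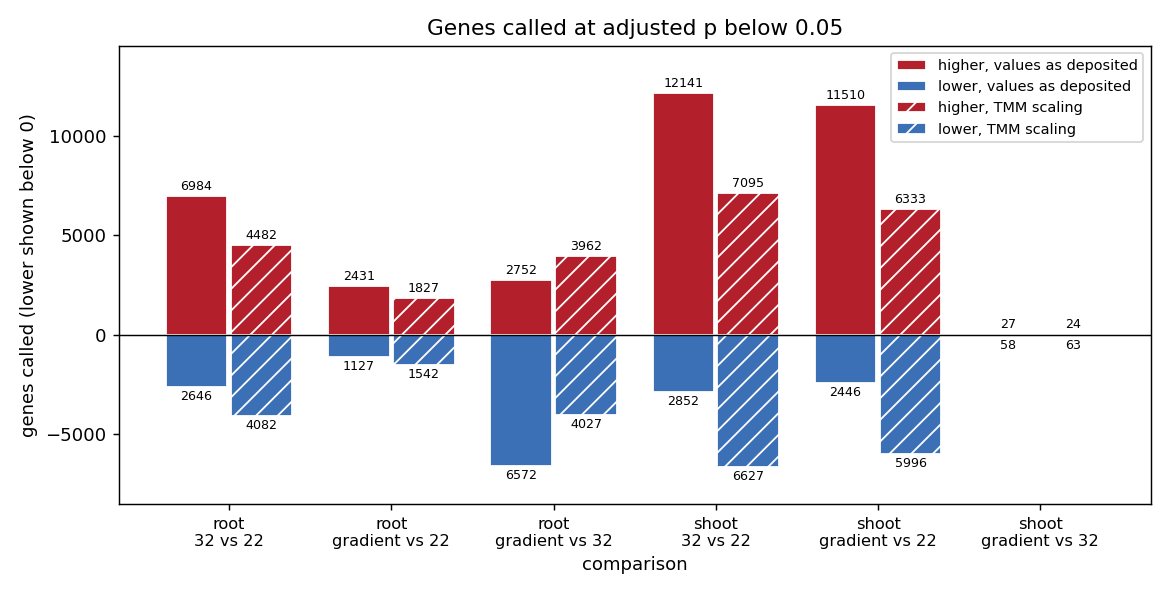
Genes called at an adjusted p below 0.05 in each of the 6 comparisons, drawn upward for genes higher and downward for genes lower in the regime named first, with the values as deposited (plain bars) and after TMM scaling within the organ (hatched bars). In 32 °C shoots 12141 genes were higher and 2852 lower than at 22 °C as deposited, against 7095 and 6627 after TMM scaling, while gradient and 32 °C shoots differed at 85 genes.

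The first comparison asked what a uniform 32 °C did to the root. HSP70 (AT3G12580), a cytosolic chaperone, went from 1530 to 19990 ± 3490 (SD, n = 3), a 12.9-fold rise, and ROF2 (AT5G48570), a heat-induced immunophilin, from 168 to 12280 ± 1420, a 72.4-fold rise. Of 29 heat shock genes 20 rose, and of 18 glucosinolate genes 15, while 13 of 19 aquaporins, 13 of 19 endodermis and suberin markers, 9 of 14 abscisic acid, 8 of 9 cold-regulated and 6 of 11 senescence and sugar starvation genes fell. No list passed in this comparison with an estimated correlation, where the lowest was an adjusted p = 0.498. The vacuolar aquaporin TIP2;3 (AT5G47450) fell from 15390 to 1663 ± 822 (SD, n = 3), and the suberin gene CYP86A1 (AT5G58860), a fatty acid hydroxylase, from 6591 to 1447 ± 416.

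Of 21877 genes tested, 9630 were called between 32 °C and 22 °C roots, 6984 higher and 2646 lower. TMM scaling brings the trimmed mean change between libraries near 0, so a median near 0 and a near-even split largely follow by construction. They do not tell which scaling is right. TMM scaling moved the median log2 fold change of all genes from 0.29 to 0.03 and changed the split to 4482 higher and 4082 lower, so log2 fold changes after TMM scaling are also given for some genes. The scaling moved those of the genes named in this comparison by -0.26 to -0.11.

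Among 29 measured heat shock proteins and factors, 20 rose, 5 fell and 4 were not called, with 20 and 5 also adjusted over the list alone and 19 and 5 after TMM scaling. The list stood above other genes (camera adjusted p = 0.000166), with an adjusted p = 0.498 with an estimated correlation. The log2 fold change of HSP70 was 3.69 ± 0.21 (SE, adjusted p = 5.22e-05), or 3.44 after TMM scaling. HSP90.1 (AT5G52640) rose from 637 to 12570 ± 2160 (SD, n = 3), and the heat shock factor HSFA2 (AT2G26150) from 12 to 162 ± 30.6. The disaggregase HSP101 (AT1G74310) rose 2.52-fold. The mitochondrial small heat shock protein gene HSP23.6 (AT4G25200) was listed at 0 at 22 °C and reached 2253 ± 372 (SD, n = 3). Of 10 genes of the unfolded protein response of the endoplasmic reticulum, 7 rose and 3 were not called, with 7 adjusted over the list alone and 7 after TMM scaling (camera adjusted p = 0.0158, and adjusted p = 0.538 with an estimated correlation). The chaperone BIP1 (AT5G28540) rose 2.95-fold to 20550 ± 1380, and the co-chaperone ERDJ3B (AT3G62600) 3.89-fold to 8572 ± 488 (SD, n = 3 for both).

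Glucosinolates are sulfur-rich defence compounds of this family. Of 18 measured genes of their synthesis, 15 rose and 3 were not called, with 17 adjusted over the list alone and 11 after TMM scaling. The list test gave a camera adjusted p = 0.000128, and an adjusted p = 0.498 with an estimated correlation. The regulator MYB28 (AT5G61420) rose from 407 to 1830 ± 184 (SD, n = 3), and MAM3 (AT5G23020), a chain-elongating synthase, from 985 to 8957 ± 869. Of 16 genes of S phase and DNA replication 10 rose and 6 were not called, with 10 adjusted over the list alone and 6 after TMM scaling (camera adjusted p = 0.0136, and adjusted p = 0.538 with an estimated correlation). Of 10 root meristem and cap markers 7 rose and 3 were not called, with 7 adjusted over the list alone and 5 after TMM scaling, at a median of 0.82 (camera adjusted p = 0.111, and adjusted p = 0.538 with an estimated correlation). The helicase subunit gene MCM3 (AT5G46280) rose 2.31-fold. The mitotic cyclin gene CYCB1;1 (AT4G37490) was not called, at 310 and 267 ± 41.6 (SD, n = 3).

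Of 19 aquaporins 13 fell, 1 rose and 5 were not called, with 15 and 1 adjusted over the list alone and 14 and 1 after TMM scaling. The camera adjusted p was 1.7e-06, with an adjusted p = 0.498 with an estimated correlation. TIP2;3 had a log2 fold change of -3.34 ± 0.49 (SE, adjusted p = 0.0015), or -3.6 after TMM scaling, and TIP2;2 (AT4G17340) fell from 33180 to 7605 ± 2520 (SD, n = 3). The plasma membrane aquaporin PIP2;5 (AT3G54820) was the member that rose, from 141 to 729 ± 105. Of 19 endodermis and suberin markers, genes of the root's inner diffusion barrier, 13 fell, 1 rose and 5 were not called, with 15 and 1 adjusted over the list alone and 14 and 1 after TMM scaling. Their camera adjusted p was 6.42e-07, and the adjusted p = 0.498 with an estimated correlation. The Casparian strip gene CASP4 (AT5G06200) fell from 1983 to 442 ± 175, the fatty acyl reductase gene FAR5 (AT3G44550) from 2763 to 458 ± 82.8 and the suberin regulator MYB41 (AT4G28110) from 425 to 45.3 ± 10 (SD, n = 3 for each).

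Of 14 genes of the abscisic acid and dehydration response 9 fell and 5 were not called, with 9 adjusted over the list alone and 9 after TMM scaling (camera adjusted p = 6.13e-06, and adjusted p = 0.498 with an estimated correlation). RAB18 (AT5G66400), a dehydrin, fell from 165 to 8.33 ± 1.53 (SD, n = 3), and the transcription factor gene RD26 (AT4G27410) from 3012 to 395 ± 27. Of 9 cold-regulated genes 8 fell and 1 was not called, with 8 adjusted over the list alone and 8 after TMM scaling (camera adjusted p = 3.16e-06, and adjusted p = 0.498 with an estimated correlation). CBF1 (AT4G25490), a regulator of cold acclimation, fell from 81 to 2.67 ± 1.15, and COR47 (AT1G20440) from 28690 to 11990 ± 388. Of 11 genes of senescence and sugar starvation 6 fell and 5 were not called, with 6 adjusted over the list alone and 6 after TMM scaling (camera adjusted p = 0.000205, and adjusted p = 0.498 with an estimated correlation). SAG13 (AT2G29350) fell from 377 to 2.33 ± 1.53 and DIN2 (AT3G60140), a glucosidase induced in darkness, from 2106 to 158 ± 23.3.

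PHT1;1 (AT5G43350), a phosphate transporter, rose 3.01-fold to 20120 ± 2500 (SD, n = 3). The phosphate sensor gene SPX1 (AT5G20150) was not called (adjusted p = 0.121), at 819 at 22 °C and at 1545, 1219 and 4963 in the 32 °C libraries, and without replicate 3 its adjusted p was 0.0373. Of 27 phosphate starvation genes 7 rose and 20 were not called, with 7 adjusted over the list alone (camera adjusted p = 0.167), and without 32 °C root replicate 2 the list's adjusted p was 0.0304. Single genes with large changes outside these groups included NDB4 (AT2G20800), a mitochondrial NADH dehydrogenase gene, which rose from 3 to 1032 ± 170. CYP93D1 (AT5G06900), a cytochrome P450 gene, fell from 407 to 0.333 ± 0.577. TT4 (AT5G13930), chalcone synthase of the flavonoid pathway, rose from 149 to 3315 ± 1120. PIF4 (AT2G43010), a regulator of growth in warmth, fell from 110 to 7.33 ± 3.79. YUC8 (AT4G28720), an auxin synthesis gene, rose 1.61-fold (adjusted p = 0.0136), a call that ended after TMM scaling (adjusted p = 0.061) and without 32 °C root replicate 1 (adjusted p = 0.0501). IRT1 (AT4G19690), NRT2.1 (AT1G08090) and ASN1 (AT3G47340), genes of iron uptake, nitrate uptake and asparagine synthesis, and LHCB1.1 were not called, with log2 fold changes of -0.53, 0.95, -0.41 and -0.95.

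The second root comparison set the gradient against 22 °C, where the shoot was warmer and the root zone ran from warm to cool. ROF2 rose from 168 to 2920 ± 354 (SD, n = 3) and HSP70 from 1530 to 6997 ± 434. Among lists, 16 of 29 heat shock, 12 of 27 phosphate starvation, 4 of 13 sulfur deficiency, 13 of 18 glucosinolate, 9 of 14 salicylic acid and 5 of 14 jasmonate genes rose. In turn 8 of 14 abscisic acid, 4 of 9 cold-regulated, 6 of 17 clock and 5 of 11 senescence and sugar starvation genes fell. No list passed with an estimated correlation, where the lowest was an adjusted p = 0.322. Of 21877 genes, 3558 were called, 2431 higher and 1127 lower, with a median log2 fold change of 0.09. TMM scaling gave 1827 higher and 1542 lower, at a median of 0.01, and moved the log2 fold changes of the genes named by -0.11 to 0.06.

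Of 29 heat shock genes 16 rose, 3 fell and 10 were not called, with 16 and 3 adjusted over the list alone and 16 and 3 after TMM scaling (camera adjusted p = 0.000111, and adjusted p = 0.48 with an estimated correlation). HSP17.6C (AT1G53540), a cytosolic small heat shock protein gene, rose from 3 to 164 ± 30.3 (SD, n = 3). HSP101 was not called (adjusted p = 0.331), at 440 and 581 ± 87.8. HSFA2 rose from 12 to 40 ± 11.8, a call that ended without gradient root replicate 1 (adjusted p = 0.0514), replicate 2 (adjusted p = 0.0943) or 32 °C root replicate 1 (adjusted p = 0.0644). Of 10 unfolded protein response genes 6 rose and 4 were not called, with 6 adjusted over the list alone and 4 after TMM scaling (camera adjusted p = 0.00135, and adjusted p = 0.502 with an estimated correlation). ERDJ3B rose 3.15-fold.

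Of 27 phosphate starvation genes 12 rose and 15 were not called, with 19 adjusted over the list alone and 10 after TMM scaling (camera adjusted p = 1.14e-05, and adjusted p = 0.515 with an estimated correlation). PHT1;1 rose from 6646 to 24800 ± 4670 (SD, n = 3), PHT1;2 (AT5G43370) from 21 to 241 ± 102 and the phospholipase gene PLDP2 (AT3G05630) from 79 to 609 ± 316. SPX1 rose 5.69-fold (adjusted p = 0.0368), and this call ended without gradient root replicate 1 (adjusted p = 0.0597), replicate 2 (adjusted p = 0.0906) or 32 °C root replicate 1 (adjusted p = 0.055). Of 13 sulfur deficiency genes 4 rose and 9 were not called, with 6 adjusted over the list alone and 3 after TMM scaling (camera adjusted p = 0.00129, and adjusted p = 0.322 with an estimated correlation). GGCT2;1 (AT5G26220), a glutathione-degrading enzyme, rose from 25 to 172 ± 52.8. Of 18 glucosinolate genes 13 rose and 5 were not called, with 17 adjusted over the list alone and 13 after TMM scaling (camera adjusted p = 1.92e-08, and adjusted p = 0.334 with an estimated correlation). MAM3 rose 7.19-fold to 7269 ± 1890.

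Of 14 salicylic acid defence genes 9 rose and 5 were not called, with 10 adjusted over the list alone and 8 after TMM scaling (camera adjusted p = 0.00035, and adjusted p = 0.48 with an estimated correlation). ICS1 (AT1G74710), which makes the salicylic acid precursor, rose from 275 to 1107 ± 103 (SD, n = 3), and the defence regulators PAD4 (AT3G52430) and FMO1 (AT1G19250) rose 3.35-fold and 6.96-fold. Of 14 jasmonate genes 5 rose and 9 were not called, with 5 rising and 1 falling adjusted over the list alone and 4 rising after TMM scaling (camera adjusted p = 0.0258, and adjusted p = 0.515 with an estimated correlation). The jasmonate list call ended without gradient root replicate 1 (adjusted p = 0.0799). VSP2 (AT5G24770), a vegetative storage protein gene, rose from 305 to 2915 ± 391. Among 15 root hair markers 3 rose and 12 were not called, with 4 adjusted over the list alone and 1 after TMM scaling (camera adjusted p = 0.00183, and adjusted p = 0.515 with an estimated correlation). MRH6 (AT2G03720) rose from 211 to 868 ± 48, a call that ended without gradient root replicate 2 (adjusted p = 0.0785).

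On the falling side, 8 of 14 abscisic acid genes fell and 6 were not called, with 11 adjusted over the list alone and 10 after TMM scaling (camera adjusted p = 1.51e-07, and adjusted p = 0.322 with an estimated correlation). Of 9 cold-regulated genes 4 fell and 5 were not called, with 6 adjusted over the list alone and 4 after TMM scaling (camera adjusted p = 0.00129, and adjusted p = 0.334 with an estimated correlation). RD29A (AT5G52310), of the cold-regulated list, fell from 642 to 157 ± 48.5 (SD, n = 3). Of 17 clock genes 6 fell, 1 rose and 10 were not called, with 7 and 2 adjusted over the list alone and 7 and 0 after TMM scaling (camera adjusted p = 0.00588, and adjusted p = 0.48 with an estimated correlation). Of 11 senescence and sugar starvation genes 5 fell and 6 were not called, with 7 adjusted over the list alone and 6 after TMM scaling (camera adjusted p = 0.00035, and adjusted p = 0.334 with an estimated correlation). SEN1 (AT4G35770), a dark-inducible gene, fell from 3079 to 280 ± 95.4. BGAL7 (AT5G20710), a galactosidase gene outside the lists, fell from 3571 to 112 ± 20.5. Aquaporins and endodermis markers were mostly not called: 1 of 19 aquaporins rose (camera adjusted p = 0.965), and 1 of 19 endodermis and suberin markers rose and 2 fell (camera adjusted p = 0.0956). TT4, PIF4, YUC8, CYCB1;1, IRT1, NRT2.1, ASN1 and LHCB1.1 were not called, with log2 fold changes of 1.78, -2.91, 0.09, -0.22, 0.03, 1.22, -0.44 and -0.35. After TMM scaling IRT1 stood at -0.05, and PIF4 passed (adjusted p = 0.0499). TT4 passed without 32 °C root replicate 3 (adjusted p = 0.0464) or gradient root replicate 1 (2.19, adjusted p = 0.0116). Without gradient root replicate 3 PIF4 (-3.39, adjusted p = 0.0196), NRT2.1 (1.82, adjusted p = 0.0217) and LHCB1.1 (-1.87, adjusted p = 0.0495) passed. The count of called genes was 1355 without gradient root replicate 2 and 6582 without replicate 3.

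The third root comparison, gradient against 32 °C, asked what a cooler root zone changed at the same shoot temperature. HSP70 stood in the gradient at 6997 ± 434 against 19990 ± 3490 (SD, n = 3 for both) and HSP23.6 at 81.7 ± 25.5 against 2253 ± 372. TIP2;3 stood at 16250 ± 2690 against 1663 ± 822, CYP86A1 at 4049 ± 635 against 1447 ± 416 and MRH6 at 868 ± 48 against 103 ± 54.9. Of the lists, 20 of 29 heat shock genes fell, and 17 of 19 aquaporins, 15 of 19 endodermis and suberin markers, 12 of 15 root hair markers, 6 of 9 cold-regulated, 8 of 14 jasmonate and 6 of 27 phosphate starvation genes rose. No list passed here with an estimated correlation, where the lowest was an adjusted p = 0.573.

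Of 21877 genes 9324 were called, 2752 higher and 6572 lower in the gradient. TMM scaling moved the median log2 fold change from -0.19 to -0.02 and the split to 3962 higher and 4027 lower. The scaling moved the log2 fold changes of the genes named by 0.08 to 0.18. The count was 5370 to 10650 when 1 library was left out. Chloroplast and mitochondrial loci held 0.21% to 0.3% of the total in gradient roots, 0.67% to 1.19% in 32 °C roots and 0.56% in the 22 °C root library, and the cause was not tested.

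**Figure D2:**
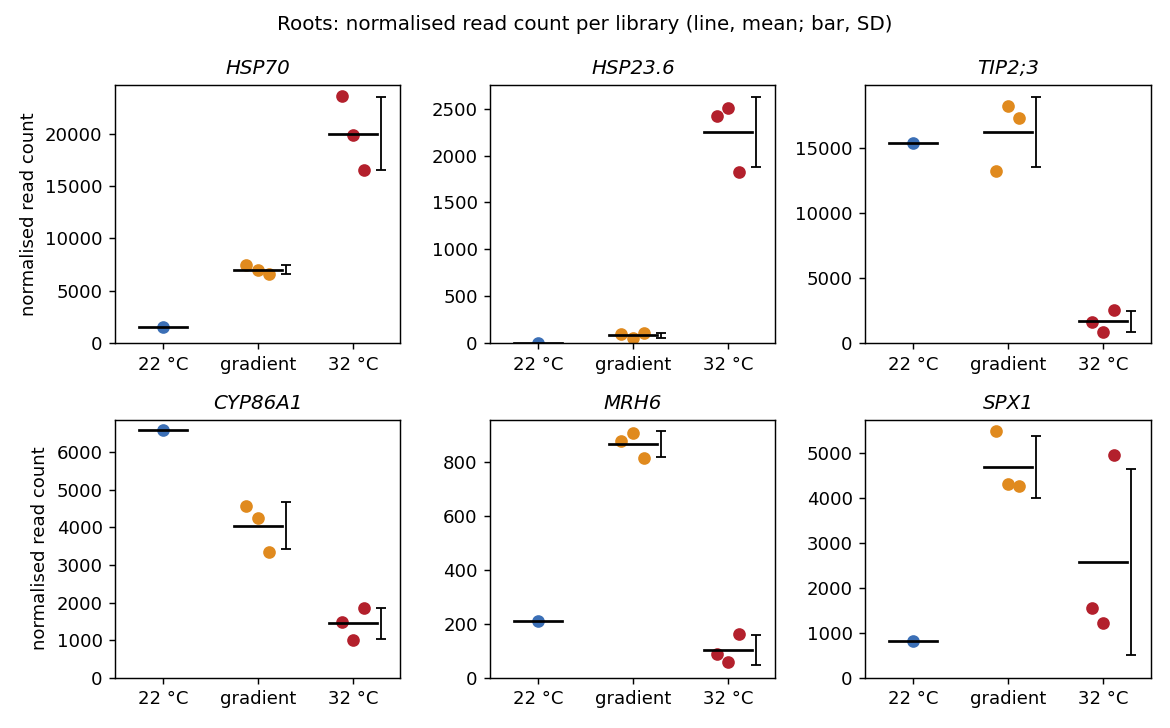
Normalised read count of 6 genes in each root library (points) at 22 °C, in the gradient and at 32 °C, with the group mean as a line and the SD as a bar where a group has more than 1 library. HSP70 and HSP23.6 are highest at 32 °C, while TIP2;3, CYP86A1 and MRH6 are lower at 32 °C than in the gradient, and SPX1 at 32 °C spreads from 1219 to 4963.

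Of 29 heat shock genes 20 fell, 3 rose and 6 were not called, with 22 and 4 adjusted over the list alone and 18 and 4 after TMM scaling. The camera adjusted p was 0.000206, and the adjusted p = 0.573 with an estimated correlation. HSP70 had a log2 fold change of -1.5 ± 0.15 (SE, adjusted p = 0.00075), or -1.33 after TMM scaling. HSP101 fell from 1127 ± 239 to 581 ± 87.8 (SD, n = 3), HSFA2 from 162 ± 30.6 to 40 ± 11.8 and ROF2 from 12280 ± 1420 to 2920 ± 354. TT4 fell from 3315 ± 1120 to 552 ± 228. ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle, fell from 22403, 38006 and 9340 in the 32 °C libraries to 519, 402 and 328 in the gradient. DOGT1 (AT2G36800), a hormone glucosyltransferase gene, fell from 551 ± 116 to 2 ± 2, a log2 fold change of -7.78, or -7.13 without gradient root replicate 2.

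Of 19 aquaporins 17 rose, 1 fell and 1 was not called, with 17 and 2 adjusted over the list alone and 17 and 1 after TMM scaling (camera adjusted p = 1.66e-09, and adjusted p = 0.573 with an estimated correlation). TIP2;3 rose by a log2 fold change of 3.41 ± 0.35 (SE, adjusted p = 0.000808), or 3.58 after TMM scaling. TIP2;2 rose from 7605 ± 2520 to 40750 ± 6600 and PIP2;4 (AT5G60660) from 2209 ± 987 to 10720 ± 1490 (SD, n = 3). Of 19 endodermis and suberin markers 15 rose, 1 fell and 3 were not called, with 15 and 1 adjusted over the list alone and 15 and 1 after TMM scaling (camera adjusted p = 4.8e-09, and adjusted p = 0.573 with an estimated correlation). CASP4 rose 3.63-fold, CASP5 (AT5G15290) 2.65-fold and FAR5 3.27-fold.

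Of 15 root hair markers 12 rose and 3 were not called, with 13 adjusted over the list alone and 13 after TMM scaling (camera adjusted p = 1.42e-08, and adjusted p = 0.573 with an estimated correlation). The expansin gene EXPA7 (AT1G12560) rose from 402 ± 233 to 2146 ± 442 and the peroxidase gene PRX73 (AT5G67400) from 537 ± 375 to 4024 ± 1380 (SD, n = 3). RHD6 (AT1G66470), which acts early in root hair fate, was not called, at 578 ± 42.6 and 627 ± 52.4. Of 10 root meristem and cap markers 5 fell and 5 were not called, with 6 adjusted over the list alone, and 4 fell and 1 rose after TMM scaling (camera adjusted p = 0.172). The stem cell regulator PLT1 (AT3G20840) fell from 736 ± 92.5 to 284 ± 27.

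Of 9 cold-regulated genes 6 rose and 3 were not called, with 6 adjusted over the list alone and 6 after TMM scaling (camera adjusted p = 0.000482, and adjusted p = 0.573 with an estimated correlation). COR47 rose 1.88-fold and CBF3 (AT4G25480) 4.28-fold. Of 14 jasmonate genes 8 rose and 6 were not called, with 8 adjusted over the list alone and 8 after TMM scaling (camera adjusted p = 4.54e-05, and adjusted p = 0.573 with an estimated correlation). VSP1 (AT5G24780) rose from 1935 ± 378 to 7836 ± 1670 (SD, n = 3). Of 27 phosphate starvation genes 6 rose and 21 were not called, with 0 adjusted over the list alone and 6 after TMM scaling (camera adjusted p = 0.000206, and adjusted p = 0.72 with an estimated correlation). PHT1;9 (AT1G76430) rose 5.89-fold (adjusted p = 0.0224), a call that ended without any of 4 libraries, namely replicates 1 and 2 of each regime (adjusted p = 0.0556, 0.0746, 0.0521 and 0.0615). Its log2 fold change of 2.56 was 1.83 without 32 °C root replicate 1 and 3.46 without replicate 3. SPX1 and PHT1;1 were not called (adjusted p = 0.0759 and 0.226), and without 32 °C root replicate 3 the adjusted p of SPX1 was 0.00131, while PHT1;1 passed without gradient root replicate 3 (adjusted p = 0.0352). Of 34 green tissue genes 1 rose and 33 were not called (camera adjusted p = 0.00972, and adjusted p = 0.812 with an estimated correlation), and this list call ended without gradient root replicate 3 (adjusted p = 0.508) or 32 °C root replicate 3 (adjusted p = 0.0878). IRT1 rose 1.48-fold at an adjusted p = 0.0492, and leaving out any library of these 2 regimes gave an adjusted p from 0.051 to 0.159. CYP82C4 (AT4G31940), an iron-responsive cytochrome P450 gene, rose from 4.33 ± 1.53 to 73.3 ± 28.3. YUC8 fell from 427 ± 35.8 to 282 ± 4.04, and PIF4, CYCB1;1, NRT2.1, ASN1 and LHCB1.1 were not called, with log2 fold changes of 0.96, 0.01, 0.27, -0.03 and 0.60. After TMM scaling ASN1 stood at 0.15.

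The 2 root contrasts that share the 32 °C libraries were set against each other. Of the 9630 genes called between 32 °C and 22 °C, 5982 (62.1%) were called in the opposite direction between the gradient and 32 °C, 4627 higher and then lower and 1355 lower and then higher. That split depended on scaling, and after TMM scaling 2599 were higher and then lower and 2232 lower and then higher. As deposited the total was 3628 without 32 °C root replicate 1, 3877 without replicate 2 and 3739 without gradient root replicate 2. Independent lists of these sizes would share 2098 and 333. In 100 simulations of unchanged groups sharing the 32 °C libraries there were 0 such genes. Unchanged genes are rarely called, so this count was near 0 by construction. It does not tell how far shared libraries raise the overlap among genes that changed. Only 158 genes were called in the same direction in both. Across genes, which are not independent replicates, the fold changes had a correlation of -0.71 against -0.35 in the simulations, and a covariance of -0.686 against -0.0295. The 32 °C libraries are too few to split into groups of 2, so part of the excess may come from those shared libraries. HSP70, ROF2, TIP2;3, CYP86A1 and COR47 were among the genes called both ways. The contrasts of 32 °C and of the gradient with 22 °C shared 2928 genes in direction, 2022 higher and 906 lower, where independent lists would share 776 and 136. After TMM scaling they shared 1447 higher and 1319 lower. Their covariance was 0.70 against 0.0882 in simulations. Their correlation was 0.71 against 0.75 in simulations, and the single 22 °C library they share cannot be split.

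The first shoot comparison asked what a uniform 32 °C did to the shoot. HSP70 rose from 618.5 ± 248 (SD, n = 2) to 9521 ± 1770 (SD, n = 3) and ROF2 from 86 ± 1.41 to 10800 ± 1740. TT4 rose 53.1-fold to 10900 ± 1860, and SPX1 11.2-fold to 3934 ± 1190. The light-harvesting gene LHCB1.4 (AT2G34430) stood at 20740 ± 1680 against 255000 ± 993 at 22 °C. Among lists, 25 of 29 heat shock, 25 of 27 phosphate starvation, 12 of 13 sulfur deficiency, 21 of 23 flavonoid and 19 of 19 glucosinolate genes rose, and 27 of 35 photosynthesis genes fell. With an estimated correlation the lowest was an adjusted p = 0.409.

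Of 21877 genes 14993 were called, 12141 higher and 2852 lower. TMM scaling moved the median log2 fold change from 0.49 to 0.04 and the split to 7095 higher and 6627 lower. The scaling moved the log2 fold changes of the genes named by -0.46 to -0.23. Chloroplast and mitochondrial loci held 0.85% to 0.93% of the total at 22 °C and 1.21% to 1.3% at 32 °C. The 100 most abundant shoot genes held 25.2% of the total at 22 °C and 18.4% at 32 °C.

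**Figure D3:**
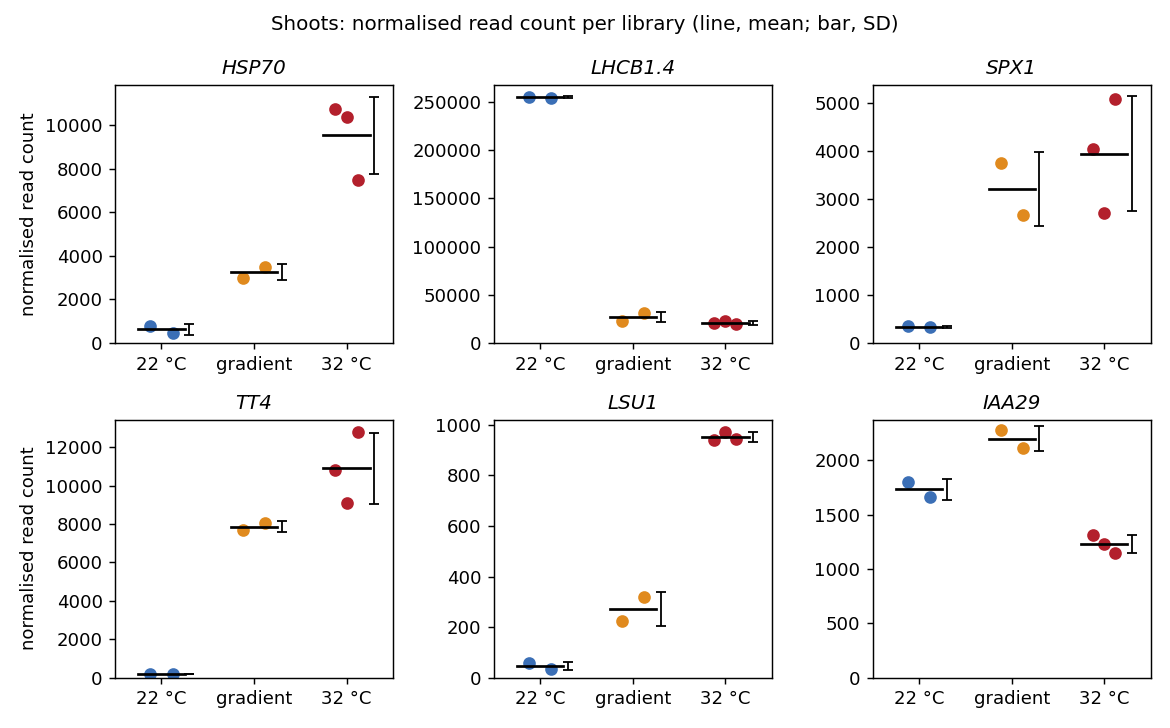
Normalised read count of 6 genes in each shoot library (points) at 22 °C, in the gradient and at 32 °C, with the group mean as a line and the SD as a bar. HSP70, SPX1, TT4 and LSU1 are lowest and LHCB1.4 is highest at 22 °C, while IAA29 averages 2200 in the gradient and 1232 at 32 °C.

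Of 29 heat shock genes 25 rose, 3 fell and 1 was not called, with 25 and 3 adjusted over the list alone and 24 and 4 after TMM scaling (camera adjusted p = 9.97e-05, and adjusted p = 0.489 with an estimated correlation). HSP70 had a log2 fold change of 3.98 ± 0.25 (SE, adjusted p = 8.54e-06), or 3.53 after TMM scaling. HSP18.2 (AT5G59720) rose from 38.5 ± 2.12 (SD, n = 2) to 2231 ± 171 (SD, n = 3), HSP22.0 (AT4G10250) from 1 ± 1.41 to 3006 ± 259 and the peroxidase gene APX2 (AT3G09640) from 0.5 ± 0.707 to 1071 ± 204. HSP101 rose 2.89-fold and HSFA2 9.39-fold. Without replicate 1 or 2 at 22 °C the log2 fold change of HSFA2 moved from 3.23 to 4.02 or 2.44, and that of HSP22.0 from 10.76 to 9.97 or 11.55. Of 11 unfolded protein response genes 9 rose and 2 were not called, with 9 adjusted over the list alone and 8 after TMM scaling (camera adjusted p = 0.00135, and adjusted p = 0.409 with an estimated correlation). BIP1 rose 5.9-fold and ERDJ3B 7.36-fold.

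Of 27 phosphate starvation genes 25 rose and 2 were not called, with 25 adjusted over the list alone and 24 after TMM scaling (camera adjusted p = 5.37e-05, and adjusted p = 0.657 with an estimated correlation). PS2 (AT1G73010), a phosphatase gene, rose from 41.5 ± 9.19 (SD, n = 2) to 4184 ± 1830 (SD, n = 3), SPX3 (AT2G45130) from 5 ± 0 to 558 ± 270, and SQD1 (AT4G33030), which makes sulfolipid, 7.96-fold. PHT1;1 rose 4.2-fold. Of 13 sulfur deficiency genes 12 rose and 1 was not called, with 12 adjusted over the list alone and 12 after TMM scaling (camera adjusted p = 0.000128, and adjusted p = 0.409 with an estimated correlation). The sulfate-reducing enzyme genes APR1 (AT4G04610) and APR3 (AT4G21990) rose 9.59-fold and 7.15-fold, and the vacuolar sulfate exporter gene SULTR4;2 (AT3G12520) 7.48-fold.

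Of 23 flavonoid and anthocyanin genes 21 rose and 2 were not called, with 21 adjusted over the list alone and 19 after TMM scaling (camera adjusted p = 9.97e-05, and adjusted p = 0.409 with an estimated correlation). The flavonol synthase gene FLS1 (AT5G08640) rose from 32 ± 0 (SD, n = 2) to 471 ± 94 (SD, n = 3), and MYB75 (AT1G56650), an activator of anthocyanin synthesis, from 4.5 ± 2.12 to 393 ± 45.4. The 19 glucosinolate genes all rose as deposited, and 18 did after TMM scaling, with 19 adjusted over the list alone (camera adjusted p = 0.000243, and adjusted p = 0.574 with an estimated correlation). The sulfotransferase gene SOT17 (AT1G18590) rose 6.13-fold.

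Of 35 photosynthesis and carbon fixation genes 27 fell, 7 rose and 1 was not called, with 27 and 7 adjusted over the list alone and 28 and 2 after TMM scaling (camera adjusted p = 1.7e-14, and adjusted p = 0.409 with an estimated correlation). LHCB1.4 had a log2 fold change of -3.62 ± 0.13 (SE, adjusted p = 1.06e-06), or -4.08 after TMM scaling, and PSAF (AT1G31330), a photosystem I gene, fell from 123900 ± 3530 (SD, n = 2) to 45350 ± 2000 (SD, n = 3). LHCB1.1 fell to 70110 ± 6500. RBCS1B (AT5G38430), a small subunit gene of Rubisco, rose from 3720 ± 29 to 23960 ± 1220. Of 19 aquaporins 9 fell, 6 rose and 4 were not called, with 9 and 6 adjusted over the list alone and 11 and 3 after TMM scaling (camera adjusted p = 0.00035, and adjusted p = 0.409 with an estimated correlation). TIP2;1 (AT3G16240) fell from 124800 ± 1740 to 41150 ± 2410. Of 11 senescence and sugar starvation genes 6 fell, 3 rose and 2 were not called, with 6 and 3 adjusted over the list alone and 7 and 2 after TMM scaling (camera adjusted p = 0.00205, and adjusted p = 0.409 with an estimated correlation). ASN1 fell from 81520 ± 15300 to 7159 ± 1340 and SEN1 from 75930 ± 18300 to 4382 ± 1140, while the sucrose transporter gene SWEET15 (AT5G13170) rose from 13.5 ± 9.19 to 1706 ± 285, a log2 fold change of 7.03, or 7.72 and 6.33 without replicate 1 and 2 at 22 °C. Of 17 clock genes 6 rose, 6 fell and 5 were not called, with 6 and 6 adjusted over the list alone and 2 and 11 after TMM scaling (camera adjusted p = 0.0179, lower than other genes, and adjusted p = 0.471 with an estimated correlation). PRR5 (AT5G24470) fell 5.88-fold.

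Root hair markers were higher in the warm shoots: 14 of 15 rose and 1 fell, the same counts adjusted over the list alone and after TMM scaling (camera adjusted p = 0.166). EXPA7 rose from 10.5 ± 3.54 (SD, n = 2) to 76 ± 27.5 (SD, n = 3) and PRP3 (AT3G62680) from 82.5 ± 3.54 to 487 ± 191. Of 18 genes of thermomorphogenesis and auxin synthesis, which act in growth in warmth, 14 rose, 3 fell and 1 was not called, with 14 and 3 adjusted over the list alone and 11 and 3 after TMM scaling (camera adjusted p = 0.325). YUC9 (AT1G04180) rose 4.37-fold, while PIF4 fell from 8132 ± 658 to 5350 ± 577 and the cell wall gene XTH15 (AT4G14130) from 9564 ± 836 to 819 ± 153. YUC8 rose 1.51-fold (adjusted p = 0.0249), a call that ended after TMM scaling (adjusted p = 0.553) and without replicate 2 at 22 °C (adjusted p = 0.195) or replicates 1 or 3 at 32 °C (adjusted p = 0.0717 and 0.0661). BAM5 (AT4G15210), a beta-amylase gene, rose from 8 ± 1.41 to values of 3745, 4089 and 29686 in the 3 libraries, a log2 fold change of 9.75, or 8.77 without replicate 3. CYCB1;1, IRT1, NRT2.1 and PR1 (AT2G14610) were not called, with log2 fold changes of 0.20, -1.47, -0.10 and -2.05, and after TMM scaling the adjusted p of IRT1 was 0.0271 and CYCB1;1 stood at -0.25. IRT1 also passed without 32 °C shoot replicate 3 (-2, adjusted p = 0.012), and PR1 without replicate 2 (-3.6, adjusted p = 0.0283).

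The second shoot comparison, gradient against 22 °C, set shoots at 32 °C over a cooler root zone against shoots at 22 °C. TT4 rose from 202.5 ± 9.19 to 7861 ± 276 (SD, n = 2 for both), ROF2 from 86 ± 1.41 to 5563 ± 457 and SPX1 rose 9.31-fold. LHCB1.4 fell from 255000 ± 993 to 27010 ± 5410. Of 21877 genes 13956 were called, 11510 higher and 2446 lower, and TMM scaling moved the median log2 fold change from 0.49 to 0.04 and the split to 6333 higher and 5996 lower. The scaling moved the log2 fold changes of the genes named by -0.45 to -0.13.

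Of 29 heat shock genes 24 rose, 3 fell and 2 were not called, with 24 and 3 adjusted over the list alone and 19 and 4 after TMM scaling (camera adjusted p = 0.00154, and adjusted p = 0.579 with an estimated correlation). HSP18.2 rose 82.8-fold to 3267 ± 119 (SD, n = 2) and HSP17.6C 325-fold to 1934 ± 281, while HSP21 (AT4G27670), a chloroplast small heat shock protein gene, was listed at 0 at 22 °C and reached 339 ± 26.9. HSP70 rose 5.43-fold and HSFA2 4.73-fold, where the log2 fold change of HSFA2 moved from 2.24 to 3.04 or 1.45 without replicate 1 or 2 at 22 °C. HSP101 rose 1.5-fold (adjusted p = 0.00663), a call that ended after TMM scaling (adjusted p = 0.358). Of 18 thermomorphogenesis and auxin synthesis genes 16 rose and 2 fell, with 16 and 2 adjusted over the list alone and 14 and 2 after TMM scaling (camera adjusted p = 0.0142, and adjusted p = 0.579 with an estimated correlation). YUC8 rose 2.09-fold, YUC9 5.36-fold and the growth regulator PRE1 (AT5G39860) 3.83-fold, and XTH15 fell 8.92-fold.

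Of 27 phosphate starvation genes 25 rose and 2 were not called, with 25 adjusted over the list alone and 23 after TMM scaling (camera adjusted p = 7.9e-05, and adjusted p = 0.618 with an estimated correlation). MGD3 (AT2G11810), a galactolipid synthase gene, rose 51.2-fold and PHT1;1 4.26-fold. The 13 sulfur deficiency genes all rose as deposited and 12 did after TMM scaling, with 13 adjusted over the list alone (camera adjusted p = 0.000851, and adjusted p = 0.579 with an estimated correlation). APR3 rose 4.86-fold. Of 23 flavonoid genes 19 rose, 1 fell and 3 were not called, with 19 and 1 adjusted over the list alone and 15 and 1 after TMM scaling (camera adjusted p = 0.00344, and adjusted p = 0.579 with an estimated correlation). All 19 glucosinolate genes rose as deposited, 17 after TMM scaling and 19 adjusted over the list alone (camera adjusted p = 0.000851, and adjusted p = 0.579 with an estimated correlation). Of 35 photosynthesis genes 27 fell and 8 rose, with 27 and 8 adjusted over the list alone and 27 and 3 after TMM scaling (camera adjusted p = 1.99e-14, and adjusted p = 0.575 with an estimated correlation). LHCB1.1 fell to 69820 ± 10800 (SD, n = 2), ASN1 fell 4.15-fold and SEN1 9.86-fold. CYCB1;1, IRT1, NRT2.1 and PR1 were not called, with log2 fold changes of 0.11, 0.19, 0.12 and -1.44. After TMM scaling CYCB1;1, IRT1 and NRT2.1 stood at -0.34, -0.24 and -0.31. The call of PIF4, which fell by 0.41 on the log2 scale, ended without 22 °C shoot replicate 2 (adjusted p = 0.0914) or gradient shoot replicate 1 (adjusted p = 0.0843).

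Of the 14993 genes called between 32 °C and 22 °C shoots, 12897 (86%) were called in the same direction between gradient and 22 °C shoots, 10741 higher and 2156 lower. After TMM scaling these were 5774 and 5483. Independent lists would share 6388 and 319. Simulated unchanged groups shared at most 1 gene in 100 draws, a count that is near 0 by construction because unchanged genes are rarely called. Across genes the correlation of the fold changes was 0.95 against 0.55 in the simulations, and the covariance 1.24 against 0.0361. The 22 °C shoot libraries cannot be split into groups of 2, so part of the excess may come from sharing them.

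The third shoot comparison, gradient against 32 °C, asked whether cooling the root zone changed shoots kept at the same temperature. In gradient shoots the sulfur deficiency gene LSU1 (AT3G49580) stood at 272 ± 66.5 (SD, n = 2) against 951 ± 18.9 (SD, n = 3) and GGCT2;1 at 79 ± 21.2 against 286 ± 26.1. The heat shock gene HSP90.1 stood at 4538 ± 148 against 10170 ± 1030 and HSP101 at 484.5 ± 4.95 against 940 ± 100. IAA29 (AT4G32280), an auxin signalling gene, was at 2200 ± 116 against 1232 ± 83 and PRE1 at 1342 ± 158 against 829 ± 23.7. Of the lists, 6 of 13 sulfur deficiency and 5 of 29 heat shock genes fell, and 3 of 18 thermomorphogenesis and auxin synthesis genes rose. No list passed here with an estimated correlation, where the lowest was an adjusted p = 0.208.

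Of 21877 genes 85 were called with limma, 27 higher and 58 lower, while 3224 had an unadjusted p below 0.05, and TMM scaling gave 87, 24 higher and 63 lower. Of these calls 0 remained without gradient shoot replicate 1 or without replicate 2-3, which leaves a group of 1 library. There were 2 calls without 32 °C shoot replicate 1 or 2, and 22 without replicate 3. The calls of the 18 genes kept here all ended without replicate 1 of the gradient shoots (adjusted p from 0.23 to 0.29) or replicate 2-3 (0.086 to 0.25), and without 32 °C shoot replicate 1 (0.0817 to 0.145) or 2 (0.11 to 0.161). Of the 18, 12 ended without 32 °C shoot replicate 3 (0.0539 to 0.117), and 3 without 22 °C shoot replicate 1 or 2 (0.0505 to 0.0579 and 0.0519 to 0.0601). With 1 or the other gradient library left out, the log2 fold change of HSP101 moved from -0.95 to -0.94 and -0.96, that of LSU1 from -1.82 to -1.57 and -2.07, and that of LDOX (AT4G22880) from -3.22 to -2.38 and -4.07. LDOX was the 1 of the 18 that moved by over 1.5 times.

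Of 13 sulfur deficiency genes 6 fell and 7 were not called, with 11 adjusted over the list alone and 5 after TMM scaling (camera adjusted p = 8.65e-12, and adjusted p = 0.208 with an estimated correlation). LSU1 fell by 1.82 ± 0.22 (SE) on the log2 scale (adjusted p = 0.0391), and BGLU28 (AT2G44460), a glucosidase gene, and APR1 fell 3.36-fold and 2-fold. Of 29 heat shock genes 5 fell and 24 were not called, with 16 falling and 2 rising adjusted over the list alone and 6 falling and 1 rising after TMM scaling (camera adjusted p = 2.96e-10, and adjusted p = 0.272 with an estimated correlation). HSP23.5 (AT5G51440) fell 2.6-fold. HSP70 was not called (adjusted p = 0.0585), at 3238 ± 368 against 9521 ± 1770, and passed after TMM scaling (adjusted p = 0.0465) and without 22 °C shoot replicate 1 or 2 (adjusted p = 0.033 and 0.0344). HSFA2 was not called (adjusted p = 0.35), at 56.5 ± 4.95 against 114 ± 21.9. HSP18.2 was not called as deposited (adjusted p = 0.0642), at 3267 ± 119 against 2231 ± 171, and passed after TMM scaling (adjusted p = 0.0454).

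Of 18 thermomorphogenesis and auxin synthesis genes 3 rose and 15 were not called, with 11 adjusted over the list alone and 3 after TMM scaling (camera adjusted p = 3.93e-12, and adjusted p = 0.208 with an estimated correlation). SAUR20 (AT5G18020), an auxin-induced gene, rose 1.69-fold. Of 23 flavonoid genes 1 fell and 22 were not called, with 11 adjusted over the list alone and 1 after TMM scaling (camera adjusted p = 1.13e-09, and adjusted p = 0.208 with an estimated correlation). LDOX, of anthocyanin synthesis, fell from 377 ± 97.8 (SD, n = 3) to 45.5 ± 34.6 (SD, n = 2), and DFR (AT5G42800) was not called (adjusted p = 0.0602), at 415 ± 66.8 and 59.5 ± 50.2. ASN1 rose from 7159 ± 1340 to 19850 ± 5450, the clock gene PRR5 rose 2.31-fold and LHY (AT1G01060) fell 1.52-fold. NUDT24 (AT5G19470), a Nudix hydrolase gene, fell from 1821 ± 323 to 143 ± 26.9. PHT1;1, SPX1, TT4, YUC8, PIF4, CYCB1;1, LHCB1.1, IRT1, NRT2.1 and PR1 were not called, with log2 fold changes of 0.02, -0.27, -0.46, 0.47, 0.20, -0.09, -0.01, 1.67, 0.22 and 0.60.

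**Figure D4:**
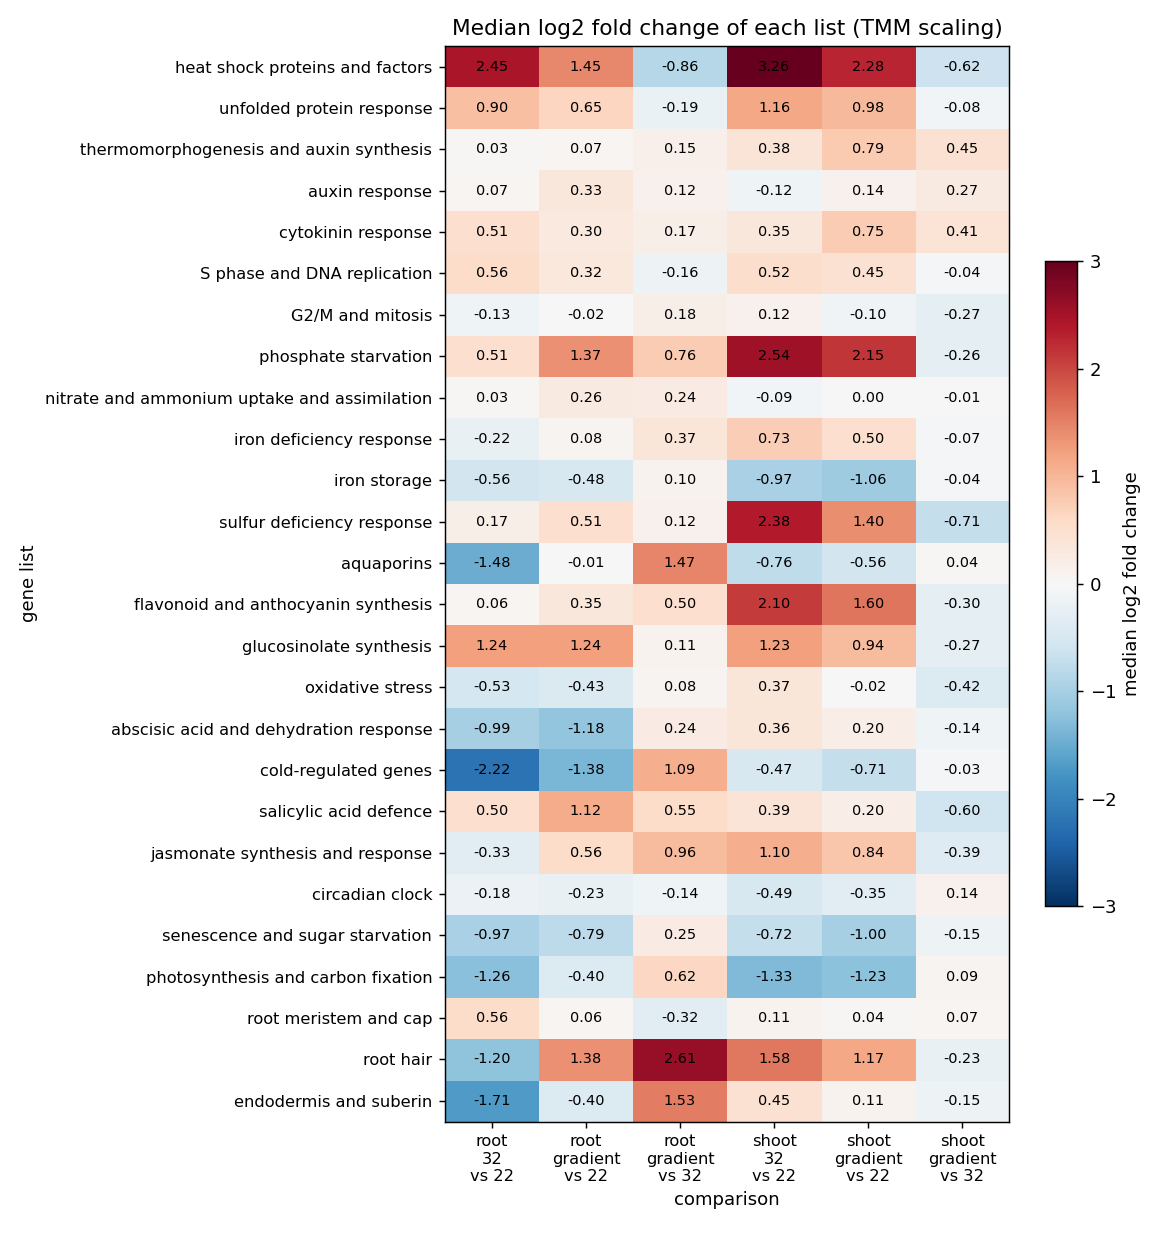
Median log2 fold change of the measured members of each gene list in the 6 comparisons after TMM scaling within the organ, with the value printed in each cell. The aquaporin list stands at -1.48 in roots at 32 °C against 22 °C and at 1.47 in gradient against 32 °C roots, while in shoots the phosphate starvation list stands at 2.54 at 32 °C and 2.15 in the gradient against 22 °C.

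Of the 14993 shoot genes, 72 were called in opposite directions between 32 °C and 22 °C and between the gradient and 32 °C, 55 higher and then lower and 17 lower and then higher, or 56 and 18 after TMM scaling. The total was 0 without either gradient shoot library, 2 without 32 °C shoot replicate 1 or 2 and 20 without replicate 3. Independent lists would share 32 and 4. Simulations of unchanged groups gave at most 1 such gene, a count that is near 0 by construction because unchanged genes are rarely called. Across genes the correlation was -0.37 against -0.40 in simulations, and the covariance -0.156 against -0.0242. Part of the excess over independent lists may come from the shared 32 °C libraries, which cannot be split. HSP101, ROF2, LSU1 and ASN1 are examples of shoot genes that gradient shoots held between the 22 °C and 32 °C levels or nearer to 22 °C, with ROF2 at 86 ± 1.41, 5563 ± 457 and 10800 ± 1740 in 22 °C, gradient and 32 °C shoots.

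Roots and shoots were compared through the interaction of organ and regime, in a fit that treated root and shoot libraries as independent although the 32 °C ones share deviations by number. At 32 °C against 22 °C 10 of 13 sulfur deficiency genes had a lower log2 fold change in the root and 3 were not called, with a median difference of -2.15 (camera adjusted p = 9.7e-06, and adjusted p = 0.137 with an estimated correlation). Of 23 flavonoid genes 18 had a lower one and 5 were not called (camera adjusted p = 5.71e-07, and 0.137 with an estimated correlation). Of 27 phosphate starvation genes 13 had a lower one and 14 not called (camera adjusted p = 0.000113, and 0.729 with an estimated correlation). Of 15 abscisic acid genes 12 had a lower one and 3 not called (camera adjusted p = 9.7e-06, and 0.313 with an estimated correlation). Only 15 flavonoid and 14 abscisic acid genes passed the root filter. The others' root response could not be judged. MYB75 differed by -6.88 (root minus shoot, adjusted p = 2.7e-05), and SAG13 by -10.97 (adjusted p = 2.83e-05). ASN1 differed by 3.1 (adjusted p = 0.00991), since it fell in the shoot and was not called in the root.

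For gradient against 32 °C 14 of 19 aquaporins had a higher fold change in the root and 5 were not called (camera adjusted p = 4.85e-11, and adjusted p = 0.245 with an estimated correlation). TIP2;3 differed by 2.96 (adjusted p = 0.0024). Of 15 root hair markers 9 had a higher fold change in the root and 6 were not called (camera adjusted p = 1.5e-08, and adjusted p = 0.407 with an estimated correlation), and of 19 endodermis and suberin markers 12 did, 1 was lower and 6 were not called (camera adjusted p = 1.25e-07, and adjusted p = 0.26 with an estimated correlation). Of 13 sulfur deficiency genes 8 had a higher fold change in the root and 5 were not called (camera adjusted p = 2.75e-05, and adjusted p = 0.245 with an estimated correlation), with LSU1 at 2.57 (adjusted p = 0.00114).

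Of 23033 genes tested in either organ, 6262 differed between organs at 32 °C against 22 °C. Of these 1721 had a higher and 4541 a lower fold change in the root. For gradient against 22 °C 6044 differed, 816 higher and 5228 lower, and for gradient against 32 °C 6268, 1853 higher and 4415 lower. TMM scaling within each organ, which brings medians near 0 by construction, moved the median differences from -0.20, -0.38 and -0.19 to 0.00, -0.02 and -0.02. It gave 3136 higher and 3507 lower, 1874 and 2532, and 2653 and 2701. Among 20721 genes tested in both organs, 5457 were higher and 979 lower at 32 °C in both, where independent lists would share 3759 and 322. Another 141 were higher in the root and lower in the shoot, and 630 the reverse. After TMM scaling 2875 were higher and 2266 lower in both, 217 were higher in the root and lower in the shoot, and 484 the reverse.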

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

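The root tissue tests, the root-enriched gene test and the thermomorphogenesis test were chosen only after the result was seen, and the tests on abundant genes and on other splits were fixed beforehand. Differences between organs are log2 fold changes in the root minus those in the shoot, tested as an interaction with limma. Rules for single outlying samples could not be applied, since no group holds 4 libraries. Single genes compared here are those kept for both organs in the same contrast, whether or not both organs' values are described.

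For 32 °C against 22 °C, 6262 genes differed between organs. HSP90.1 differed by -1.51 (adjusted p = 0.000953), with log2 fold changes of 4.29 in the root and 5.79 in the shoot. BIP1 differed by -1 (adjusted p = 0.00121) and ERDJ3B by -0.92 (adjusted p = 0.00345). ROF2 differed by -0.77 (adjusted p = 0.0343), and after TMM scaling by -0.57 (adjusted p = 0.0719). APX2 differed by -5.28 (adjusted p = 5.84e-05) and HSP22.0 by -2.39 (adjusted p = 0.0223). These 2 sizes depend on the pseudocount, since HSP22.0 was listed at 0 in the 22 °C root library and APX2 averaged 0.5 in 22 °C shoots, and they are not measured sizes of the response. PIF4 differed by -3.26 (adjusted p = 0.0109), with log2 fold changes of -3.87 in the root and -0.61 in the shoot. MAM3 differed by 1.5 (adjusted p = 0.0034) and ASN1 by 3.1 (adjusted p = 0.00991).

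For gradient against 22 °C, 6044 genes differed. ROF2 differed by -1.89 (adjusted p = 0.000369), HSP17.6C by -3 (adjusted p = 0.000393) and ERDJ3B by -1.28 (adjusted p = 0.000743). TT4 differed by -3.49 (adjusted p = 0.00152), with log2 fold changes of 1.78 in the root and 5.27 in the shoot. PIF4 differed by -2.50 (adjusted p = 0.0446) and YUC8 by -0.97 (adjusted p = 0.0274), and neither passed after TMM scaling (adjusted p = 0.091 and 0.17).

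For gradient against 32 °C, 6268 genes differed. ROF2 differed by -1.13 (adjusted p = 0.00288), TT4 by -2.16 (adjusted p = 0.00733) and YUC8 by -1.06 (adjusted p = 0.00728). HSP23.5 differed by -0.84 (adjusted p = 0.0344), and after TMM scaling by -0.67 (adjusted p = 0.0698).

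As deposited, 72.5% of the genes called at 32 °C against 22 °C in roots and 81% in shoots were higher. After TMM scaling these were 52.3% and 51.7%, and with voom weights and TMM factors together 45.7% in roots. TMM factors bring the split near even by construction, so these shares do not tell whether the excess of higher genes came from scaling. A few abundant genes that take a smaller part of the total at 32 °C could raise all others, and without the 100 most abundant genes 72.5% of the median log2 shift was left in the shoot (0.45 before and 0.33 after) and 87% in the root (0.28 and 0.24). These values argue against those 100 genes as the whole cause. Genes of lower rank, the authors' normalisation (not given) and a change in total RNA per cell stay open, and none was tested.

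Root hair markers were higher in 32 °C shoots, and taken as root RNA they imply a share of 16.3% (15 genes, from -39.2% to 27.8%). RNA of whole roots may be a source, but 249 abundant root-enriched genes reached a median of 5.01% of their root level (quartiles 2.98% and 8.09%). Of them 228 were below the implied share and 21 not. For 32 °C shoots set against 32 °C roots this argues against whole roots as the full source and leaves a smaller share open. Gradient shoots were not tested this way. In roots 12 of 15 root hair markers were higher in the gradient than at 32 °C, while in shoots 0 of 15 were called. The implied share would thus tend to be lower in gradient shoots, and the mismatch may not hold there. Tissue of all root zones would raise meristem and cap markers, and these reached a ratio of 0.0845 of the predicted rise. Mature root tissue cannot be told apart from a change in the shoot itself, since endodermis and suberin markers reached a ratio of 0.545, which meets what this source predicts, while the root-enriched genes fall short of it. Examples chosen after their values were seen are MLP328 (AT2G01520), at 2721 in 22 °C and 4414 in 32 °C shoots against 80681 in 32 °C roots, LAC7 (AT3G09220), at 712 and 1101 against 22464, EXT3 (AT1G21310), at 4510 and 16111 against 104100, and AT5G26260, at 716 and 5406 against 27957. Their rises were 2.1%, 1.73%, 11.1% and 16.8% of the root level. PYK10 (AT3G09260), too abundant in 22 °C shoots to be among the 249, rose from 58459 to 270119, by 42.7% of its root level of 495578, which is more than root RNA at the implied share would give.

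Gradient shoots may have had a uniformly smaller response to 32 °C. Lists higher at 32 °C would then have a median below 0 in gradient against 32 °C. The called heat shock, unfolded protein, phosphate, sulfur, flavonoid and glucosinolate lists did (-0.72 to -0.08). The thermomorphogenesis and auxin synthesis list, higher but uncalled at 32 °C, stood at 0.45 (SE 0.07 over its 18 genes, not over libraries). Its median was 0.34 to 0.61 in all 6 pairs of a gradient and a 32 °C shoot. Of its genes 3 were called, and it did not pass with an estimated correlation (adjusted p = 0.208). The 0.45 argues against a smaller response in this list, but not in the called ones. The cooler root zone the design names and any difference in shoot temperature stay open as untested.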

How the results depend on the processing

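The alternatives with identical columns kept separate, with voom weights and TMM factors, with other block numbers and with identical columns counted once in the filter were chosen only after the result was seen. Of the counts of called genes and of genes called in opposite directions (reversals), 179 alternatives stayed within 1.5 times and 58 did not. Of the values of named genes 4249 kept the side of the threshold, 223 lost the call and 62 gained one. The sign turned in 55, none called before or after. Of the list tests 1420 kept the side, 69 of them turning direction uncalled, 136 lost the call, 72 of these with an estimated correlation, 58 gained one and 5 turned direction with a call. All 5 turned under fry, which does not set a list against other genes: flavonoid synthesis in roots at 32 °C against 22 °C (adjusted p = 0.0385), auxin response (adjusted p = 0.0218) and salicylic acid defence (adjusted p = 0.0177) in shoots at 32 °C against 22 °C, and oxidative stress (adjusted p = 0.00446) and senescence (adjusted p = 0.0191) in gradient against 22 °C shoots. Unless stated, the cause was not tested. Tests with edgeR and DESeq2 on recovered reads were not run, because the values are described as normalised and no reads behind them were recovered.

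With library weights (arrayWeights) the counts were 16040, 13968 and 18048 for roots at 32 °C against 22 °C, gradient against 22 °C and gradient against 32 °C, 588 for gradient against 32 °C shoots, 11978, 12280 and 13885 for the differences between organs in these 3 contrasts, and 11962 and 429 for root and shoot reversals. A fold change of at least 2, which removes calls by construction, left 5436, 2022 and 2930 in roots, 6964, 6429 and 32 in shoots, and 2810 for the difference between organs in gradient against 32 °C. Identical columns kept as separate replicates, which adds libraries with no spread, gave 8804 for gradient against 22 °C roots, 1182 for gradient against 32 °C shoots, 9941 and 10030 for the differences between organs at 32 °C and in the gradient against 22 °C, and 844 shoot reversals. Fitting only the 2 groups compared gave 1417 for gradient against 22 °C roots. Voom weights and TMM factors together gave 194 for gradient against 32 °C shoots, 163 shoot reversals and 3498 for the difference between organs in gradient against 22 °C.

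Gradient against 32 °C shoots, and shoot reversals, gave 128 and 111 with a pseudocount of 8, 12 and 12 with no filter and 152 and 133 with all libraries in 1 fit.

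With the replicate number as a block the counts were 7486 for gradient against 32 °C roots, 15348, 14813 and 0 for the 3 shoot comparisons, 0 shoot reversals and 5602 for the difference between organs in gradient against 32 °C. The 22 °C root library carries 2 numbers and was left out of that fit. Numbered 1 or 2, it gave 7137 or 6754 for 32 °C against 22 °C roots, 1093 or 953 for gradient against 22 °C roots, and 6313 or 6386 for the difference between organs at 32 °C against 22 °C, where no difference named in the text changed its call. With the identical gradient shoot columns numbered 3, gradient against 32 °C shoots gave 0 and shoot reversals 0. Same-numbered libraries had correlations across genes from -0.21 to 0.02 between 32 °C and gradient roots, from -0.17 to 0.02 between 22 °C and 32 °C shoots, of 0.14 between 22 °C and gradient shoots, from -0.13 to 0.23 between 32 °C and gradient shoots and from 0.03 to 0.08 between gradient roots and shoots.

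Leaving out 1 library at a time gave ranges of 7056 to 11802, 1355 to 6582 and 5370 to 10650 in roots, 12412 to 15278, 11221 to 14740 and 0 to 115 in shoots, 4486 to 8181, 4170 to 8160 and 2929 to 7621 for the differences between organs, and 3628 to 6895 root and 0 to 103 shoot reversals. The single 22 °C root library could not be left out. In gradient against 22 °C roots, 1976 were called without 32 °C root replicate 1, 1355 without gradient root replicate 2 and 6582 without replicate 3. In gradient against 32 °C roots, 5625 and 5803 were called without 32 °C root replicates 1 and 2 and 5370 without gradient root replicate 2, and root reversals were 3628, 3877 and 3739 without these. The difference between organs in gradient against 32 °C gave 3922 and 2929 without gradient shoot replicates 1 and 2-3. Shoot reversals were 0 without either gradient shoot library, 2 without 32 °C shoot replicate 1 or 2 and 20 without replicate 3.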

Other observations

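The test on other splits was fixed beforehand, and none of the tests in this part was chosen only after the result was seen.

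Of 18 genes of the oxidative stress list 7 fell, 3 rose and 8 were not called in 32 °C against 22 °C roots, with 7 and 3 adjusted over the list alone and 8 and 3 after TMM scaling (camera adjusted p = 0.0262, and adjusted p = 0.498 with an estimated correlation). In gradient against 22 °C roots 6 fell, 1 rose and 11 were not called, with 7 and 1 adjusted over the list alone and 6 and 1 after TMM scaling (camera adjusted p = 0.00893, and adjusted p = 0.334 with an estimated correlation). In gradient against 32 °C shoots 1 fell and 17 were not called, with 5 adjusted over the list alone (camera adjusted p = 0.00189, and adjusted p = 0.208 with an estimated correlation). In those shoots 1 of 16 auxin response genes rose and 15 were not called, with 10 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00131, and adjusted p = 0.366 with an estimated correlation). Among 8 cytokinin response genes 0 were called there, with 1 rising adjusted over the list alone and a median log2 fold change of 0.41 (camera adjusted p = 0.00432, and adjusted p = 0.621 with an estimated correlation), a call that ended without gradient shoot replicate 2-3 (adjusted p = 0.139). Among 21 genes of G2/M and mitosis 0 were called there, and 0 adjusted over the list alone, at a median of -0.27 (camera adjusted p = 0.00075, and adjusted p = 0.651 with an estimated correlation), and this call ended without gradient shoot replicate 1 (adjusted p = 0.0699).

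Of 27 genes of nitrate and ammonium uptake and assimilation, 14 rose, 2 fell and 11 were not called in 32 °C against 22 °C shoots, and 10 rose and 7 fell after TMM scaling, where the median changed sign (camera adjusted p = 0.52). Of 24 iron deficiency genes 16 rose, 3 fell and 5 were not called in those shoots, and 10 rose and 5 fell after TMM scaling (camera adjusted p = 0.583). Of 4 iron storage genes 1 fell and 3 were not called in gradient against 22 °C shoots, with 1 adjusted over the list alone and 2 after TMM scaling (camera adjusted p = 0.0403, and adjusted p = 0.579 with an estimated correlation). That list call ended without 22 °C shoot replicate 1 (adjusted p = 0.271) or 32 °C shoot replicate 3 (adjusted p = 0.051). Of 11 cold-regulated genes 4 fell, 1 rose and 6 were not called in 32 °C against 22 °C shoots (camera adjusted p = 0.0179, and adjusted p = 0.854 with an estimated correlation), and the call ended without 22 °C shoot replicate 1 (adjusted p = 0.339). Among 6 seed storage genes, markers of embryos, 0 were called in any shoot comparison. In gradient against 32 °C shoots their median was 2.23 (camera adjusted p = 0.0928, and adjusted p = 0.71 with an estimated correlation). That list passed without 22 °C shoot replicate 1 or 2 (adjusted p = 0.0183 and 0.0167), 32 °C shoot replicate 3 (adjusted p = 0.0425) or gradient shoot replicate 2-3 (adjusted p = 0.0059). At 32 °C against 22 °C it stood lower than other genes (camera adjusted p = 0.162), and it passed without 22 °C shoot replicate 2 (adjusted p = 0.00382).

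Gradient and 32 °C roots were also compared under the 10 splits of their 6 libraries into groups of 3. The real split called 9324 genes and the highest other split 0, so that 1 of 10 called as many, and 10 splits are too few for a share under 0.05.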
